A study of Mus musculus with 3 samples.

How the data were processed

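The series holds 3 single-colour arrays of total RNA (Affymetrix mouse 430_2.0 chip, biotin label), each from 1 mouse bone marrow cell line immortalized by a fusion of the MLL (KMT2A) gene. Of these, 1 array came from a line named MLL-AF10(OM-LZ), called MLL-AF10 here, the control per the labels, and 2 came from MLL-EB1 lines, numbered replicate 1 and replicate 2 in the labels. EB1 is the microtubule end-binding protein encoded by Mapre1, and AF10 is encoded by Mllt10. The MLL-AF10 line and MLL-EB1 replicate 2 were derived on an EGFP-transgenic C57BL/6J strain and MLL-EB1 replicate 1 on plain C57BL/6J, so strain was not the same in both MLL-EB1 lines and could not be a covariate. The lines grew with IL3 at 10 ng/ml and 20% serum, per the labels.

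The deposited table gives log2 expression values of the authors, 45101 rows by 3 columns, and every column matched 1 sample. Per the submitters' processing notes the values came from Affymetrix Expression Console 1.2 and RMA, a method that corrects background, equalizes the distributions of the arrays and summarizes the probes of each probe set. Such equalizing can hide a shift shared by most genes of 1 array. The log2 scale was checked on the spike controls, whose ladder from BioB to Cre spanned 5.93, 6.00 and 5.87 in the MLL-AF10 line and MLL-EB1 replicates 1 and 2. The column medians were 1.47 on each array. Control probe sets for transcripts not added to the RNA had a median of 0.272, 0.272 and 0.281, below the floor usually seen with RMA, and whether the values were changed after RMA is not given in the sources used here. The highest of these absent controls on an array (0.995, 1.21 and 0.981) was taken as its floor. Where 1 group lay at or below the floor, a fold is given as at least the fold against that floor.

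Among the rows, 64 were control probe sets, 34945 had 1 gene symbol in the platform table, 932 had several and 9160 had none. Only probe sets with 1 symbol were named, and 34741 of them were matched by gene ID to the reference gene table (assembly GRCm38.p6), which updated symbols and gave the chromosome. No coordinates were used beyond gene order. For each gene the probe set with the highest mean over the 3 arrays was kept, giving 18193 genes, and 4484 genes with a value of 6 or more on at least 1 array were tested. Of the tested genes, 679 were read by a probe set of the _s_at or _x_at type, which can also bind related transcripts. As arrays carry no read depth, their number limits the precision.

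The main comparison set the 2 MLL-EB1 lines against the MLL-AF10 line with limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. This leaves 1 residual degree of freedom, so the spread came from the 2 MLL-EB1 lines and from the prior over genes (2.54 prior degrees of freedom), and the lone MLL-AF10 array was assumed to vary like them. Nothing in the labels says how many separate cultures were sampled, so p-values measure only the spread between these arrays. A second count took genes at least 2-fold apart from the MLL-AF10 line in the same direction in both MLL-EB1 lines. Between the MLL-EB1 lines, 1 array against 1, differences are given as values with no test.

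Altogether 32 gene lists were fixed before the data were examined. They covered HoxA genes with cofactors, other targets of MLL fusions, MLL complexes, microtubule ends and spindle, mitosis, DNA replication, cell cycle inhibitors with p53 targets, blood lineages and stromal cells. They also covered interferon, IL3 and STAT5, cytokines, adhesion, stress responses, metabolism, histones, sex-linked genes, genes that differ between C57BL/6 substrains, and housekeeping. The 21 lists with at least 5 tested members were compared with all other tested genes by limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists). The estimated correlation, run as an alternative, rests on the single residual degree of freedom, so hardly any list could pass with it. Its adjusted p-values therefore do not weigh for or against a list.

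The rule for named genes, fixed at the same time, took the 12 genes farthest above and the 12 farthest below the MLL-AF10 line by the smaller of the 2 lines' differences, and up to 4 members of each list by the same measure. It also took the 6 highest and 6 lowest genes between the MLL-EB1 lines, and Hoxa9, Meis1, Mapre1, Mllt10, Kmt2a, Xist, Ddx3y, Nnt, Kit and Cd34. Genes with clone-like predicted names were counted but not named, Ddx3y was not analysed here, and not every gene that the rule took is named in the text.

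The test was checked on simulated data with 50 genes changed at each size among 4484. It called 0 of 50 at a log2 change of 1, 6 of 50 at 2, 48 of 50 at 4 and 48 of 50 at 6, with 9 false calls in all. Camera found 20 of 20 simulated lists shifted by 1 (log2), and 5% of unshifted lists had an unadjusted p under 0.05. The simulated genes varied independently, whereas members of a real list can vary together. The check therefore does not show that camera's p-values hold for the real lists. The simulated gene changes of all sizes shared the same fit, which eases the adjustment for each, so their shares called may not hold for the real data. There, differences of -6.54 (Dsp) and 4.64 (Rnf128) were not called, so a lack of calls does not exclude changes of that size. The alternatives were other brightness filters, scalings, ways to pick probe sets, priors, thresholds and leaving out each MLL-EB1 line. After the data were seen, a filter at log2 3 and leaving out the genes of chromosome 6 were added. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.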

Results

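Genome-wide expression was measured on 3 arrays, with 1 MLL-AF10(OM-LZ) line, called MLL-AF10 below, as the control and 2 MLL-EB1 lines. All were mouse bone marrow cells immortalized by a fusion of MLL, a histone methyltransferase gene often rearranged in acute leukaemia. The question put by the design was which genes differ between cells carrying the EB1 fusion and cells carrying the AF10 fusion. In the 3 lines, 6346 (MLL-AF10), 6114 (MLL-EB1 replicate 1) and 6156 (MLL-EB1 replicate 2) probe sets reached a log2 value of 6. Levels below are normalized log2 expression, errors are SDs over the 2 MLL-EB1 lines unless called SE, and the MLL-AF10 line had no replicate. Over the 4484 tested genes, the Pearson correlation across genes, which are not independent replicates, was 0.905 between MLL-AF10 and MLL-EB1 replicate 2. It was 0.841 between MLL-AF10 and replicate 1, and 0.815 between the MLL-EB1 lines.

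The genes of the fusion partners stood within 2-fold of the MLL-AF10 line on the probe sets kept. Mapre1, which encodes EB1, stood at 8.37 ± 0.12 (SD, n = 2) in the MLL-EB1 lines and 8.45 in the MLL-AF10 line, and over its 4 probe sets the difference ranged from -0.38 to 0.07. Mllt10, which encodes AF10, stood at 6.63 ± 0.19 against 7.19, a difference of -0.56 (SE 0.31; -0.43 in replicate 1, -0.69 in replicate 2, and -0.76 on its other probe set), where the median absolute difference of tested genes was 0.16. Kmt2a was at 5.10 ± 0.05 against 5.11, below the filter, with a difference of -0.44 on its other probe set. The sources used here do not give whether these probe sets read the fusion transcripts, so these values do not check the labels. Hoxa9, a homeobox gene kept active by MLL fusions, was high in all 3 lines, at 9.54 in MLL-AF10 and 10.27 and 9.72 in MLL-EB1 replicates 1 and 2. Its cofactor gene Meis1 stood at 6.33, 6.84 and 5.97. Xist was at 1.04 to 1.36, and the Y-linked gene Eif2s3y at 7.34, 6.72 and 7.61. Nnt, which is disrupted in the C57BL/6J substrain, was at 7.10, 6.55 and 6.56 on an _x_at probe set.

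Both MLL-EB1 lines stood at least 2-fold below the MLL-AF10 line at 51 genes and at least 2-fold above it at 26. This balance depended on the filter, with 9 below and 12 above when the mean over the arrays had to reach log2 6. The lower genes were led by Dsp, which encodes the desmosome protein desmoplakin. Its level was 7.42 in the MLL-AF10 line, 0.59 (under the floor) in replicate 1, at least 74.0-fold lower, and 1.18 in replicate 2, 75.6-fold lower. Its probe set was of the _s_at type, and of the gene's 3 probe sets the least different gave -2.37. Mecom, which encodes the stem cell transcription factor EVI1, was at 7.46 against 1.02 (under the floor) and 3.59. The light chain gene Myl10 was at 8.50 against 4.89 and 1.74. F13a1, the coagulation factor XIII A chain of monocytes and platelets, was 7.04-fold lower at 6.64 ± 0.16 (SD, n = 2) against 9.46. The neighbouring membrane protein genes Tmem176a and Tmem176b were 6.70-fold and 7.71-fold lower, with Tmem176a differences from -2.77 to -1.59 over its 3 probe sets. Thy1 (8.33-fold lower, at 4.45 ± 0.80), Itih5, Ahnak, the matrix gene Tgfbi (_x_at, -4.13 to -2.70 over 4 probe sets) and the MHC class II gene H2-Aa (_x_at, -1.70 on its other probe set) completed the genes farthest below, with Cd34.

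Among the genes farthest above the MLL-AF10 line, the ubiquitin ligase gene Rnf128 was 24.9-fold higher. It stood at 5.65 ± 0.62 (SD, n = 2) against 1.02, just above the floor of 0.995, a difference of 4.64 (3.88 on its other probe set). F7, which encodes coagulation factor VII, was 34.3-fold higher in replicate 1 and 3.73-fold in replicate 2. In the same order Glyat (_s_at, mean difference 3.57 on its other probe set) was 30.4-fold and 11.1-fold, Zbtb8a 19.8-fold and 9.30-fold, the transcription factor gene Ets1 13.6-fold and 4.67-fold, and Mcemp1 9.46-fold and 5.16-fold higher. Thbs1, which encodes the secreted matrix protein thrombospondin 1, was 6.25-fold higher at 8.20 ± 0.26, and the actin-binding protein gene Afap1 5.88-fold higher. The chemokine gene Ccl3 was at 7.64 ± 0.09 against 5.42, a 4.67-fold difference. Clec4d (_s_at), a lectin receptor gene of myeloid cells, and Dennd11 were 4.12-fold and 3.81-fold higher. Clec4d, Dennd11, Tmem176a and Tmem176b lie on chromosome 6, whose genes had a median 0.48 (log2) higher in MLL-EB1 replicate 1 than in the other 2 arrays.

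**Figure D1:**
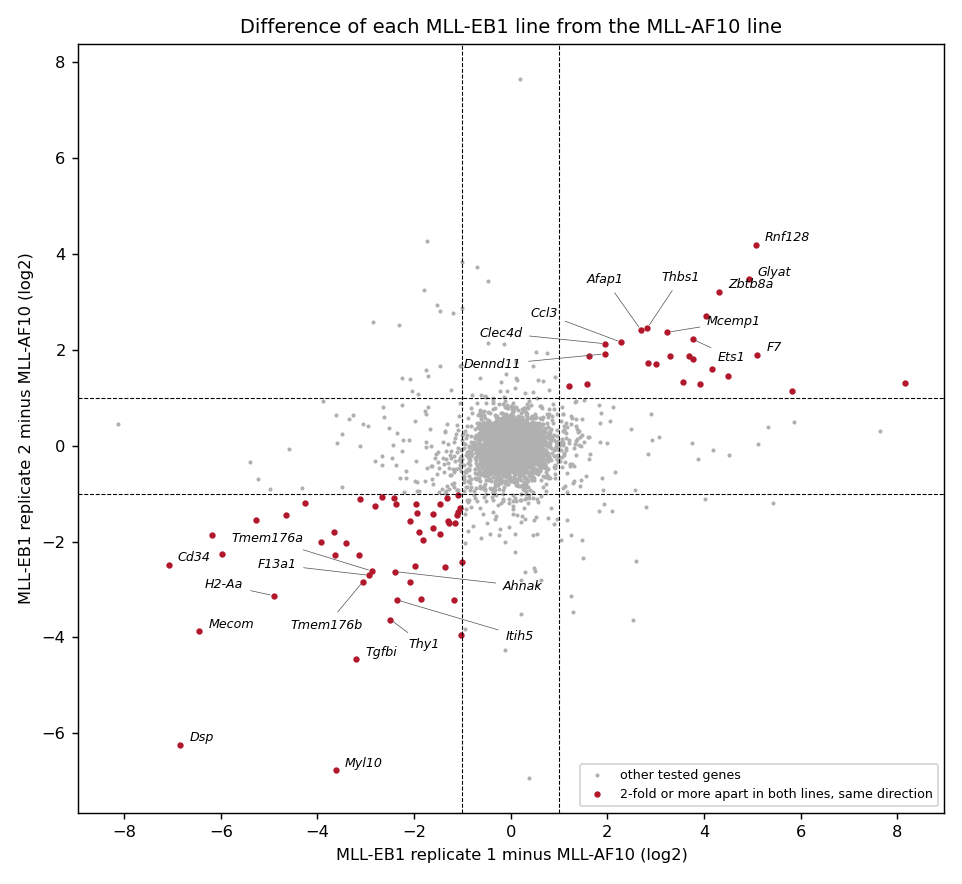
Each point is 1 of 4484 tested genes, with its log2 difference from the MLL-AF10 line in MLL-EB1 replicate 1 (horizontal) and in replicate 2 (vertical), and dashed lines mark 2-fold. Red points are the 77 genes at least 2-fold apart in the same direction in both lines, 26 above and 51 below, with the genes farthest from the MLL-AF10 line that the text names labelled.

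Genes of late neutrophils were divided. Of 14 measured members, 7 were higher in both MLL-EB1 lines, 3 were lower in both and 4 went opposite ways. Here and in the lists below, such counts took any difference of the same sign, however small. Cd177 and Ltf, for example, were only 0.051 and 0.047 (log2) higher in replicate 2. The calprotectin genes S100a8 (_s_at) and S100a9 were 5.99-fold and 7.38-fold higher, at 10.77 ± 1.00 and 9.85 ± 1.81 (SD, n = 2) against 8.19 and 6.97, with S100a8 9.76-fold and S100a9 17.9-fold higher in replicate 1, and 3.67-fold and 3.04-fold in replicate 2. Ngp, a granule protein gene, was 6.96-fold higher at 9.54 ± 1.39 against 6.74 (13.7-fold in replicate 1, 3.52-fold in replicate 2), and Pglyrp1, a peptidoglycan receptor gene, was 3.15-fold lower. The list's median difference was 0.85 (1.65 in replicate 1, 0.40 in replicate 2), and camera gave an adjusted p of 0.1999. The direction of this median depended on the filter, as it was 0.08 with no filter and -0.18 with genes down to log2 3. At log2 3 the medians were -0.01 in replicate 1 and 0.20 in replicate 2, the mean difference 0.26 and the camera direction up. Among 15 primary granule and promyelocyte genes, 4 were higher and 3 lower in both lines, with a median of -0.05 (0.24 in replicate 1, -0.20 in replicate 2), a camera direction up and an adjusted p of 0.627. Cst7, which encodes cystatin F, was 12.9-fold higher in replicate 1 and 3.64-fold in replicate 2, and Nkg7 2.04-fold and 15.4-fold lower, while Ctsg, which encodes cathepsin G, stood at 11.91 ± 0.18 against 11.69.

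Among 16 monocyte and macrophage genes, 2 were higher and 8 lower in both lines, with a median of -0.79 (-1.63 in replicate 1, -0.07 in replicate 2) and an adjusted p of 0.142. F13a1 and the perforin-like gene Mpeg1 (9.30 against 6.64 and 8.23) were among the lower genes, and the neighbouring lectin receptor genes Clec4d and Clec4e were the 2 higher ones. Adjusted over the list alone, limma called 3 of the 16, F13a1 (adjusted p = 0.0204), Clec4d (0.0278) and Clec4e (0.0352), and over all tested genes it called 0. Both lectin genes lie on chromosome 6. They stood 2.13 and 1.88 (log2) above MLL-AF10 in replicate 2, where the chromosome's median difference was -0.04. The chromosome's shift in replicate 1 thus does not account for their levels in replicate 2. Leaving out the chromosome takes the 2 higher genes from the list and leaves 13 members, so the values that follow rest in part on their removal. Without the genes of that chromosome, a setting added after the data were seen, the list had a median of -1.06 (-1.77 in replicate 1, -0.26 in replicate 2) and an adjusted p of 1.08e-04, and 0.839 as adjusted p with an estimated correlation. Dendritic cell and MHC class II genes had 4 measured members, 0 higher and 3 lower in both lines, among them H2-Aa (6.23 against 1.32 and 3.10) and Cd74, the invariant chain gene (7.27 against 2.03 and 6.56).

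Of 10 stem and progenitor genes, 2 were higher and 5 lower in both lines (median -0.33, with -0.23 in replicate 1 and -0.60 in replicate 2, adjusted p = 0.189). Cd34, a surface marker gene of progenitors, was at 7.77 in MLL-AF10, at 0.68 (under the floor) in replicate 1 and at 5.29 in replicate 2. Sox4 was at 7.84 against 5.86 and 7.10, and Cd48 at 7.62 against 6.09 and 7.03. With genes down to log2 3 admitted, a filter added after the data were seen, the monocyte, MHC class II and stem lists passed camera (adjusted p = 0.0046, 0.0013 and 0.0090). Their medians were -0.87 (-1.36 in replicate 1, -0.25 in replicate 2), -1.63 (-1.92 and -1.09) and -1.004 (-0.999 and -0.59), and all 3 had an adjusted p of 0.881 with an estimated correlation.

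**Figure D2:**
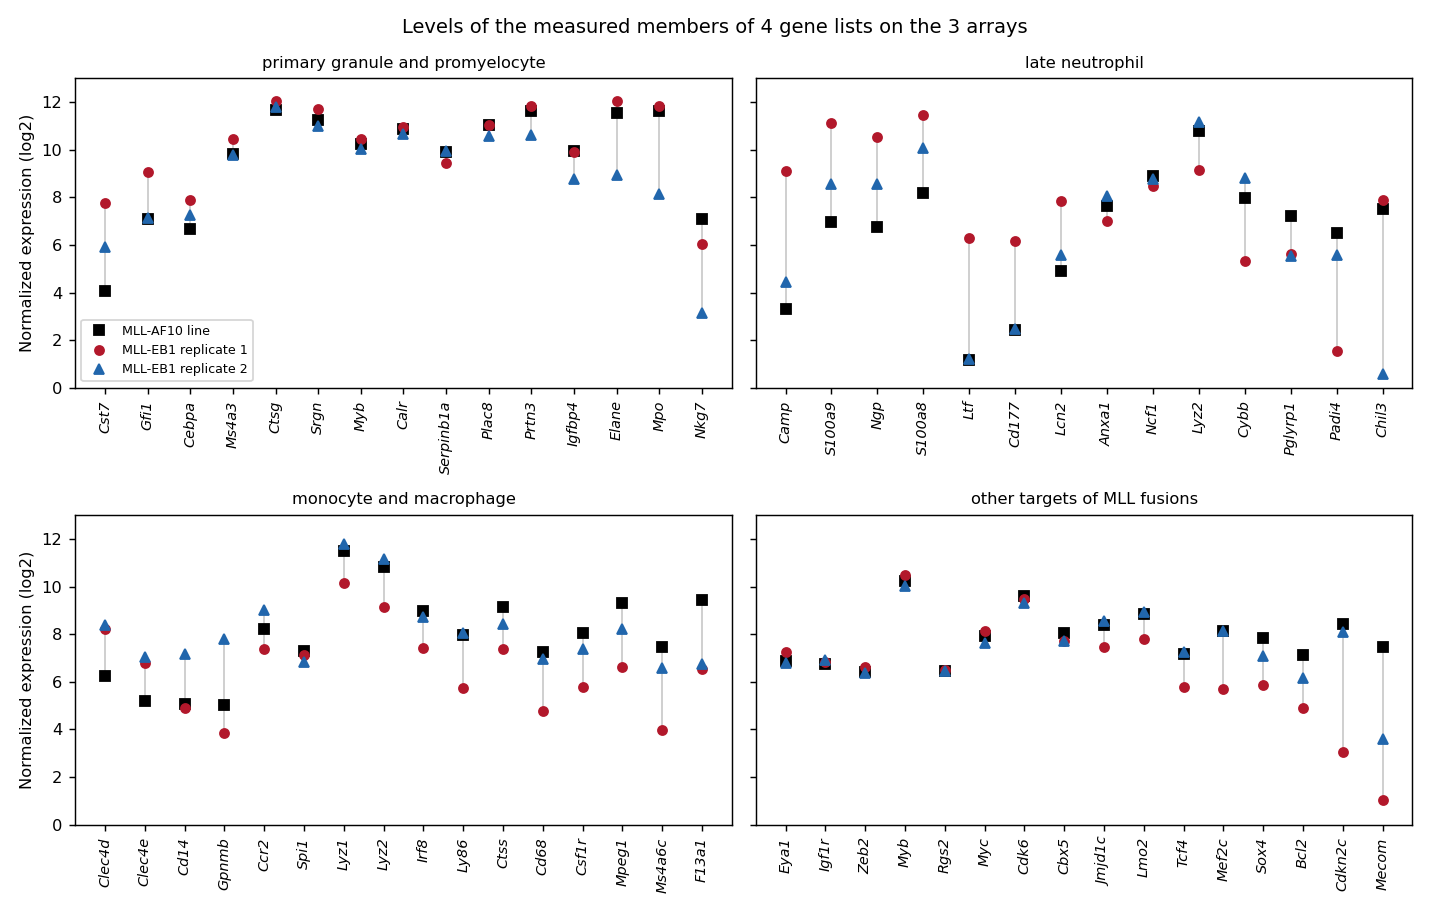
Normalized log2 expression (vertical) of every tested member of 4 gene lists, ordered within each list by the mean difference of the MLL-EB1 lines from the MLL-AF10 line, with 1 point per array and a grey line for their range. Black squares are the MLL-AF10 line, red circles MLL-EB1 replicate 1 and blue triangles replicate 2; the S100a8, S100a9 and Ngp points of both MLL-EB1 lines lie above those of the MLL-AF10 line, and those of F13a1, Mpeg1 and Mecom below.

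HoxA genes and cofactors had a median of 0.45 (0.51 in replicate 1, 0.17 in replicate 2) over 5 measured members, with Hoxa9 and Hoxa10 higher in both lines. Hoxa10 was at 5.80 in MLL-AF10, 7.85 in replicate 1 and 6.33 in replicate 2. The other 3 members went opposite ways. Among them Hoxa11, picked after its values were seen, was at 2.30 in MLL-AF10, 1.61 in replicate 1 and 6.04 in replicate 2. The list's adjusted p was 0.0693, and its median was 0.29 with genes down to log2 3 (-0.001 in replicate 2, adjusted p = 0.489) and 0.16 with no filter (adjusted p = 0.667). HoxA genes lie on chromosome 6, where the median of replicate 1 was higher. Other targets of MLL fusions had 1 gene higher, 6 lower and 9 opposite among 16, a median of -0.35 (-0.62 in replicate 1, -0.13 in replicate 2) and an adjusted p of 0.0693. When the arrays were quantile normalized again the list's adjusted p was 0.0488, or 0.845 as adjusted p with an estimated correlation. Its median was -0.13 with no filter (adjusted p = 0.0692) and -0.32 with genes down to log2 3 (-0.06 in replicate 2, adjusted p = 0.0774). Besides Mecom, the lower genes included the survival gene Bcl2 (4.63-fold lower in replicate 1, 1.96-fold in replicate 2, 5.53 ± 0.88 against 7.12) and the cell cycle inhibitor gene Cdkn2c (8.43 against 3.04 and 8.08). In the list of MLL, its fusion partners and their complexes, 2 of 9 were higher and 3 lower (median -0.07, with 0.01 in replicate 1 and -0.05 in replicate 2, adjusted p = 0.777).

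The microtubule list, which holds Mapre1, had 2 genes higher and 13 lower in both lines among 24, a median of -0.15 (-0.19 in replicate 1, -0.12 in replicate 2) and an adjusted p of 0.189. With no filter the list passed camera (33 genes, median -0.13, adjusted p = 0.0066), as did DNA replication (0.0266), core histone (0.00996), monocyte (0.0066), MHC class II (0.0025) and stem genes (0.0054), all with 0.875 as adjusted p with an estimated correlation. The spindle motor gene Kif11 was at 6.56 ± 0.05 (SD, n = 2) against 6.98, and Stmn1 (_s_at), which encodes the tubulin-binding protein stathmin, at 9.92 ± 0.09 against 10.36. Mitosis genes had 1 higher and 9 lower of 23 (median -0.06, with -0.11 in replicate 1 and -0.09 in replicate 2, adjusted p = 0.471), and DNA replication genes 1 higher and 14 lower of 23 (median -0.11, with -0.16 and -0.05, adjusted p = 0.329). Top2a stood at 8.94 ± 0.03 against 9.29 and Mcm7 (_s_at) at 9.77 ± 0.04 against 10.11. Of 7 cell cycle inhibitors and p53 targets 3 were lower in both lines (median -0.04, with -0.49 in replicate 1 and 0.66 in replicate 2, adjusted p = 0.671), among them Sesn1 (_s_at), at 6.65 ± 0.05 against 7.10. The other 4 (Ccng1, Cdkn1a, Mdm2 and Zmat3) were lower than in MLL-AF10 in replicate 1 and higher in replicate 2.

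Among genes of the IL3 receptor and STAT5, 2 were higher and 4 lower of 12 (median -0.23, with -0.32 in replicate 1 and -0.21 in replicate 2, adjusted p = 0.1999). The feedback inhibitor gene Socs2 was 3.14-fold lower at 5.64 ± 0.27 against 7.29, and the kinase gene Jak2 2.60-fold lower at 5.13 ± 0.32 against 6.52. Cytokines and chemokines had 2 higher and 2 lower of 6 (median 0.06, with 0.26 in replicate 1 and 0.49 in replicate 2, adjusted p = 0.0693), with Ccl3 and Ccl9 above the MLL-AF10 line. Genes of the unfolded protein and amino acid response were higher in both lines in 8 of 18 and lower in 3 (median 0.12, with 0.17 in replicate 1 and 0.15 in replicate 2, adjusted p = 0.0693). The folate enzyme gene Mthfd2, on chromosome 6, was at 7.75 ± 0.09 against 6.92, and the amino acid transporter gene Slc7a5 at 7.85 ± 0.23 against 7.31. Cholesterol synthesis genes were higher in 8 of 13 and lower in 1 (median 0.12, with 0.37 in replicate 1 and 0.04 in replicate 2, adjusted p = 0.0693), with Sc5d at 6.82 ± 0.15 against 6.10. The unfolded protein and cholesterol lists passed with the filter at log2 3 (adjusted p = 0.0071 and 0.0142, both with 0.881 as adjusted p with an estimated correlation).

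The remaining tested lists did not pass either. Adhesion molecules and surface receptors had 7 higher and 4 lower of 21 (median -0.03, with 0.05 in replicate 1 and 0.26 in replicate 2, camera direction up, adjusted p = 0.492), with the integrin gene Itga4 2.31-fold lower and Cd33 1.90-fold higher. Glycolysis and hypoxia genes had 3 higher and 6 lower of 16 (median -0.12, with -0.25 in replicate 1 and -0.01 in replicate 2, adjusted p = 0.471), and heat shock genes 2 higher and 2 lower of 8 (median 0.06, with -0.11 and 0.33, adjusted p = 0.471). None of the 5 mast cell and basophil genes (median 0.21, with 0.54 in replicate 1 and -0.23 in replicate 2, adjusted p = 0.471) or the 5 immediate early genes (median -0.14, with -0.26 and 0.18, adjusted p = 0.671) had the same direction in both lines. Housekeeping genes had 1 higher and 1 lower of 12 (median -0.02, within 0.01 of 0 in each line, camera direction up, adjusted p = 0.716).

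Markers of other cell types were mostly below the filter. Erythroid genes had 1 measured member, sex-linked markers 1, interferon response genes 2 and eosinophil genes 0, none with the same direction in both lines. Megakaryocyte and platelet genes had 3, of which Thbs1 was higher in both lines, and stromal and endothelial genes 3, of which Thy1 and the fibronectin gene Fn1 were lower. Ighm, on an _s_at probe set, was the 1 measured B cell gene (2.18-fold lower, with other probe sets reaching 0.19), and Thy1 the 1 measured T and NK cell gene. Of 3 core histone genes H2ax and H2az1 were lower in both lines, and of 3 genes that differ between C57BL/6 substrains Nnt was lower in both. Adjusted over the list alone, limma called Thbs1, Thy1, Ighm and Ccl3 in these short lists and the cytokine list, with lists of 1 to 6 measured genes. In a list of 1 gene, as for Ighm and for Thy1 among T and NK cell genes, this is the unadjusted p. No adjustment was made over the lists, and over all tested genes limma called 0.

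In the limma fit 0 of 4484 genes passed at an adjusted p under 0.05, the lowest being 0.776 for Dsp, lower in both lines, which rests in part on a value under the floor, and 0 of 21 lists passed camera. At an unadjusted p under 0.05 there were 86 genes, where 224.2 would come by chance, and 57 of them were among the 77 genes 2-fold apart in both lines. Without moderation of the spread limma called 4 genes, named here after their values were seen (Abcc4, Ptcd3, Smc3 and Srrt), each with an SD of 0 between the MLL-EB1 lines and a difference between -0.26 and 0.40. With an estimated correlation no tested list passed, but that setting rests on 1 residual degree of freedom, with which hardly any list could pass. The 77 genes share 1 control array. Unchanged lines simulated against a shared control gave 157.6 such genes on average (122 to 186 over 100 simulations), more than the 77 observed. The simulated spread of each gene was taken from the difference between the 2 MLL-EB1 lines. These lines were 2-fold apart at 433 genes, against 320 and 221 genes from the MLL-AF10 line. The simulated count may thus be too high, and it cannot decide whether a shared control alone gives 77 genes. Independent lists would share 2.21 higher and 6.07 lower genes.

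The 2 MLL-EB1 lines differed from each other at least 2-fold at 433 genes, 254 higher in replicate 1 and 179 higher in replicate 2. This was more than the 320 and 221 genes that set replicate 1 and replicate 2 apart from the MLL-AF10 line. These are differences between single arrays, with no replicate check, and the lines also differ in mouse strain. Higher in replicate 1 were the collagen gene Col6a3 (8.57 against 1.22), the myelin protein gene Pmp22 (8.78 against 1.94) and Ppp1r14c (8.10 against 1.47). Chil3, a chitinase-like gene of neutrophils and macrophages, was at 7.88 in replicate 1 and at 0.57, under the floor, in replicate 2, at least 119.6-fold lower. The glutathione peroxidase gene Gpx3 (8.95 against 2.79) and Myo7a (7.38 against 2.02) followed. Higher in replicate 2 were App, the amyloid precursor gene, at 9.44 against 0.86, under the floor, and the cathepsin inhibitor gene Stfa3 (8.78 against 1.32). Penk (7.51 against 1.501), the T cell costimulation gene Cd28 (7.01 against 1.57), Cdkn2c (8.08 against 3.04) and the histidine decarboxylase gene Hdc (_s_at, 6.90 against 1.87) were also higher there.

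Myeloid genes were among those that set the MLL-EB1 lines apart. Of 15 primary granule genes 7 were at least 2-fold higher in replicate 1 and 0 in replicate 2, and of 16 monocyte genes 0 were higher in replicate 1 and 12 in replicate 2. Of 14 late neutrophil genes 8 were higher in replicate 1 and 4 in replicate 2, and of 16 other MLL fusion targets 0 and 8. Kit, the stem cell factor receptor gene, was at 7.32 in replicate 1 and 3.87 in replicate 2. The following genes were picked after their values were seen. Mpo, which encodes myeloperoxidase, was at 11.85 in replicate 1, 8.13 in replicate 2 and 11.65 in MLL-AF10, and Elane, which encodes neutrophil elastase, at 12.05, 8.93 and 11.55. Camp, which encodes cathelicidin, was at 9.11, 4.43 and 3.29. The D cyclin gene Ccnd2 was at 4.81, 9.06 and 8.42, Ccnd1 at 2.94, 6.84 and 3.41, and Mycn at 5.92, 9.79 and 6.92.

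Taken by chromosome, over genes of log2 3 or more, replicate 1 had a median difference of 0.48 from the mean of the other 2 arrays on chromosome 6 (441 genes, 95% bootstrap interval over genes 0.43 to 0.53). On the other chromosomes its medians lay between -0.09 and -0.02. MLL-AF10 and replicate 2 differed on chromosome 6 by a median of -0.04. Without the genes of chromosome 6 the counts were 68 genes 2-fold apart from MLL-AF10 in both lines and 382 between the MLL-EB1 lines.

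**Figure D3:**
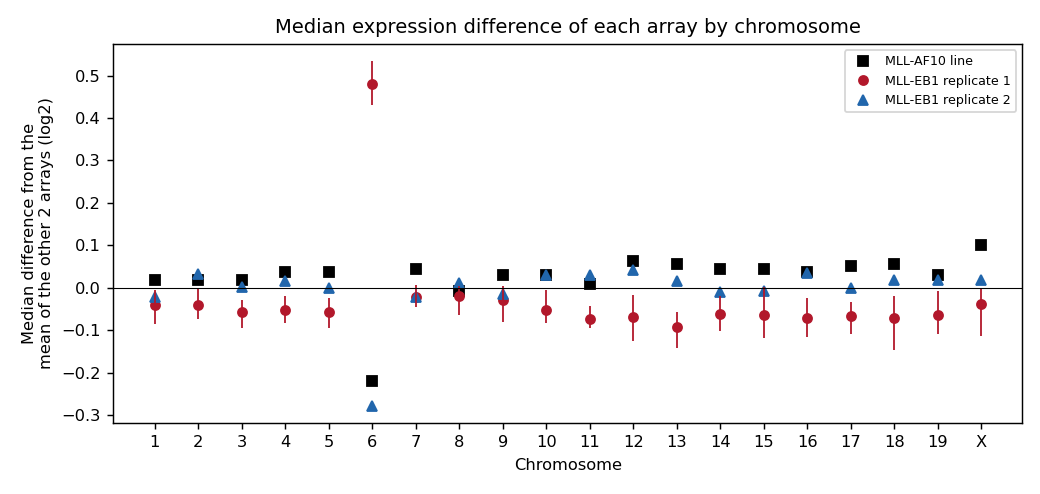
For each chromosome (horizontal), the median over genes of log2 3 or more of each array's log2 difference from the mean of the other 2 arrays (vertical), with black squares for the MLL-AF10 line, red circles for MLL-EB1 replicate 1 (bars are 95% bootstrap intervals over genes) and blue triangles for MLL-EB1 replicate 2. Chromosome 6 stands at 0.48 in MLL-EB1 replicate 1, while its other chromosomes lie between -0.09 and -0.02.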

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

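The comparisons leave out probe sets that the platform table ties to no gene or to several. Among 689 such probe sets with a log2 value of 6 or more on at least 1 array, 1 was at least 2-fold higher in both MLL-EB1 lines than in the MLL-AF10 control line, and 8 were at least 2-fold lower. That is 0.145% higher and 1.16% lower, against 0.580% and 1.14% of the tested genes, so these probe sets show no excess of higher values. The probe set that was higher was not tested further and is not named, since its gene is not settled. With groups of 1 and 2 arrays, no check for single outlying arrays within a group was possible.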

How the results depend on the processing

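The filter at log2 3 and leaving out chromosome 6 were chosen after the data were seen. For the MLL-EB1 lines against the MLL-AF10 line, limma called 0 genes in every setting run except without moderation, where it called 4, all with identical values on both MLL-EB1 arrays, so that their spread was 0. Unadjusted counts under 0.05 were 77 with an intensity trend and 140 without moderation. The count of 77 genes 2-fold apart in both lines was 259 with no filter (59 higher, 200 lower), 214 with the filter at 3, 36 at 7, 21 with a mean of 6 (12 higher, 9 lower), 47 with the mean of a gene's probe sets, and 27 at 4-fold. With 1 line left out there were no residual degrees of freedom and so no limma count. The 2-fold rule then asks for only the other line, which must give at least as many genes, 320 for replicate 1 and 221 for replicate 2. The count of 433 between the MLL-EB1 lines was 1166 with no filter, 1034 at 3, 242 at 7, 248 with a mean of 6 and 258 with the mean of probe sets. Filters change how many genes are counted, and so did the mean of a gene's probe sets, which left 2479 tested genes against 4484. The cause of the other shifts was not tested. The number of lists passing camera was 6 with no filter, 5 at 3, 1 after quantile normalization and 1 without chromosome 6, against 0; each was 0 with an estimated correlation. With an estimated correlation hardly any list could pass, since that setting rests on 1 residual degree of freedom. The late neutrophil median turned from 0.85 to -0.18 at log2 3, where the list's mean difference was 0.26. Of 21 list medians 4 changed sign without replicate 1 and 4 without replicate 2, and 2 after quantile normalization. Quantile, median and cyclic loess scaling gave 74, 78 and 72 genes with the filter and probe sets chosen again, and 74, 77 and 73 of the 77 genes kept the rule on the probe sets first chosen, with no new filter; between the lines they gave 439, 430 and 448. The median of all tested genes moved by under 0.1 in each. Of 109 named genes 0 changed sign under the 3 scalings, 5 with the highest of their probe sets, and 4 and 6 without replicate 1 and replicate 2. Most named genes were picked for having the same direction in both lines, so leaving out a line could not change their sign. The counts of 4 and 6 therefore do not measure how stable the directions are. Of the 77 genes, 9 had a second probe set of log2 6 or more, and in 9 it had the same direction. Low values limit the folds. Only values at or below the floor were treated as bounds. Folds on values just above it, such as Rnf128 in MLL-AF10 (1.02) and Dsp in replicate 2 (1.18), are uncertain. No paired analysis was possible because the groups share fewer than 2 replicate numbers.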

Other observations

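The tests for degraded RNA, mouse strain, an extra chromosome, the HoxA genes and the arrays set alone were chosen only after the result was seen. Below the brightness filter, 4626 genes had their highest value between log2 3 and 6, and 30 of them were at least 2-fold higher and 107 at least 2-fold lower in both MLL-EB1 lines. The genes that follow were picked after their values were seen. By the smaller of the 2 lines' differences, taken before any bound from the floor, the farthest below was Fstl1, which encodes a secreted follistatin-like protein, at 4.69 in MLL-AF10 and under the floor in both MLL-EB1 lines, at least 12.1-fold lower. Aff3, a relative of the MLL partner gene Aff1, was 18.3-fold lower, the lipid transporter gene Spns2 16.3-fold and the receptor kinase gene Grk3 15.1-fold. Klf4, a transcription factor gene of monocytes, was at 5.35 against 2.01 and 2.05. By the same measure the farthest above were Greb1 (10.8-fold), Slfn4, a schlafen gene of myeloid cells (9.13-fold), and Nt5e, which encodes the ectoenzyme CD73 (7.69-fold). Dixdc1 (5.93 in replicate 1, 3.802 in replicate 2) and the iron exporter gene Slc40a1 (4.78 and 2.64) were also higher in both lines, and both were under the floor in MLL-AF10.

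A first pattern was the shift of chromosome 6 in MLL-EB1 replicate 1. Its median of 0.480 lay outside the range of 1000 random relabellings of genes to chromosomes (-0.133 to 0.077), which argues against chance scatter of chromosome medians. The lowest median over the 3 equal parts of the chromosome in gene order was 0.463, which argues against a few co-regulated clusters. A candidate explanation is an extra copy of the chromosome in that line: 88.2% of its genes lay above the median of all other genes, and the shift over those genes was 0.53 where 3 copies against 2 would give 0.58, but no DNA was measured here and the strain of that line stays open. The HoxA genes, on the same chromosome, had a median difference of 0.43 from MLL-AF10 in replicate 1, at percentile 45.0 of the chromosome's other genes, but 3 of the 5 were higher and 2 (Hoxa7, Hoxa11) lower, so whether the chromosome's shift accounts for their levels stays open.

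A second pattern was that replicate 1 stood apart from both other arrays at 209 genes, against 121 for MLL-EB1 replicate 2 and 77 for MLL-AF10, and limma called 0 genes for each array set alone (435, 198 and 86 at an unadjusted p under 0.05), or 12 for replicate 1 after cyclic loess. Degraded RNA is argued against by the 3' minus 5' differences of Actb and Gapdh, which lay within 0.0700 of the other arrays. Under 3 further scalings the ratio of replicate 1's count to the next array's was at least 1.71, so the choice among these does not account for it. The deposited values were already equalized by RMA, so an effect of that first step was not excluded. Without chromosome 6 the counts were 183, 113 and 68. Mouse strain cannot be told apart from the line itself, since only 1 array is of that strain. Setting each array alone in turn, 3 of 3 splits gave as many genes as the real one (77, highest other 209), and 3 splits are too few for a share under 0.05.

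Another pattern was the set of 79 genes at least 8-fold apart between the MLL-EB1 lines, 37 of them higher in replicate 1. For 18 of these genes a fault of single probe sets is argued against by their 25 second probe sets, of which 100% differed at least 2-fold in the same direction. Only second probe sets of log2 6 or more on at least 1 array were counted, so dimmer ones that could disagree were left out. For the other genes this was not tested. A difference between lines carrying the same fusion, such as clone or stage of differentiation, stays open and was not tested.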
